A study of Zea mays with 20 samples.

How the data were processed

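Maize plants of inbred background B73, per the labels, were sampled as young leaves (a tube 7 to 8 mm long and 1 to 2 mm wide taken 2 to 3 mm above the SAM at 10 days), as field-grown tassel primordia (pools of 10) and ear primordia (pools of 6 to 8), and as shoot apical meristems (pools of 15 at 19 days). Total RNA was extracted with Trizol and libraries were made with an Illumina TruSeq RNA kit, which keeps no strand, so reads of genes that overlap on opposite strands cannot be told apart. The authors named CASAVA 1.8, TopHat 1.2.0, HTSeq and DESeq 1.4.1 in their processing notes, without the role or order of each; the genome build and annotation of the files were not given in the sources used here. The deposited table holds raw counts per gene for 39656 genes, with 1 column per library, and 8181 genes had 0 counts in all 20 libraries. Titles call the tassel, ear and SAM controls wild type, their genotype label reads kn1-e1/+, and the design names heterozygote or wild-type plants; they are called siblings here. The comparison tables that the labels name were not used here.

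Gene names came from the reference table of Zm-B73-REFERENCE-NAM-5.0, in which 18775 gene IDs (47.3%) matched, 520 of them to more than 1 gene, and 2639 had a name. Neighbours of kn1 were taken from the gene order of that assembly, which the counts do not have to share.

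Counts were fitted with edgeR 4.0.16 (quasi-likelihood F test, TMM factors, filterByExpr with a count minimum of 10 and a total of 15) in R 4.3.3, separately for leaf (6 libraries, 3 genotypes), tassel (6), ear (4) and SAM (4), which left 3, 4, 2 and 2 residual degrees of freedom; edgeR shares information on spread between genes. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. The differences between tissues were tested in 1 fit of the 14 tassel, ear and SAM libraries. Standard errors were computed from the F statistic and the log2 fold change and are approximate. Where a group had 1 to 3 counts, the ratio of summed counts was given with its exact 95% interval; such intervals cover counting error only. The biological coefficient of variation was 0.0540 in leaf, 0.0485 in tassel, 0.0526 in ear and 0.0853 in SAM. The same fits were tested on simulated data with 200 changed genes. They recovered 94.0% (homozygous leaf), 86.6% (heterozygous leaf), 92.5% (tassel), 91.0% (ear) and 73.1% (SAM) of 1.5-fold changes. Of 2-fold changes they recovered 97.0 to 100%, and there were 6 to 10 false calls. The changed genes were drawn from the better expressed genes only. Counts followed the trend of spread with expression, without extra spread of single genes or libraries. Recovery in the real data may therefore be lower.

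Depth by group, in counts per library, was 16542370 to 20599373 in homozygous, 20535139 to 20670084 in heterozygous and 18922133 to 19500856 in wild-type leaf, and 17602429 to 19548798 in kn1-e1 and 18540771 to 19006899 in sibling tassel. It was 19450891 to 20722952 in kn1-e1 and 16584659 to 19433572 in sibling ear, and 16972390 to 19056230 in kn1-e1 and 16068246 to 18924945 in sibling SAM.

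The comparisons, tests, alternatives, the 28 gene lists and the rule for naming genes were chosen before the data were examined; the symbols that match each list were looked up in the reference table afterwards, before any test. The lists were KNOX and BELL homeobox, inflorescence and meristem architecture, gibberellin, cytokinin, auxin, brassinosteroid, jasmonate, ethylene, abscisic acid, MADS-box, TCP, YABBY, SBP-box, growth-regulating factors, LOB domain, HD-ZIP and other leaf polarity, histones, cell cycle and DNA replication, cytosolic ribosomal proteins, photosynthesis, cell wall loosening and cellulose, lignin and phenylpropanoid, cuticle and wax, vascular tissue, pollen and anther, heat shock and chaperones, defence and circadian clock. Lists with at least 5 tested members were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over 125 tests in the 5 comparisons with a control, with an estimated correlation and fry beside it. Camera compares a list with all other genes, whereas fry asks only whether its genes move. With a preset correlation camera counts genes rather than libraries as its units. With an estimated one it has only the residual degrees of freedom of the fit, 2 to 4 here, and so little power after adjustment. Neither adjusted p alone settles whether a list moved. The jasmonate list took in lipoxygenase genes by symbol, whatever their product.

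The rule named, in each comparison, kn1; up to 3 called members by smallest p from each of the 6 lists with the most calls and from the KNOX and inflorescence lists; the 5 largest increases and 5 largest decreases among named, called genes of at least 1 CPM whose groups did not overlap; and the 5 named genes with the smallest p that moved oppositely in homozygous leaf and at least 2 kn1-e1 tissues. Overlaps of calls were compared with independent lists (the product of the list sizes over the genes tested in both) by Fisher's exact test, two-sided, and 20 simulations gave the likeness that shared wild-type leaf libraries alone produce.

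The alternatives were DESeq2 1.42.0, size factors by relative log expression, library totals only, no filter or a filter at a mean of 1 CPM, an adjusted p of 0.01, all 20 libraries in 1 fit, a replicate block, only the genotypes compared, and leaving out each library. Residuals of libraries with the same replicate number were not alike, so replicate numbers were not taken as pairs. No batch is given in the labels. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.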

Results

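Messenger RNA from maize plants that gain or lose activity of KNOTTED1 was counted in 20 libraries. The gene kn1 (GRMZM2G017087) encodes a KNOX homeobox transcription factor of shoot meristems. The dominant allele Kn1-N was followed in young leaves of homozygotes, heterozygotes and wild type (2 libraries each). The loss-of-function allele kn1-e1 was followed in tassel primordia (3 mutant and 3 sibling libraries), in ear primordia (2 and 2) and in the shoot apical meristem (SAM; 2 and 2). Libraries held 16068246 to 20722952 counts, and 24810 to 26394 genes had at least 1 count. The 10 most abundant genes took 2.12 to 2.70% of the counts. Changes below are log2 fold changes of the first group over the second ± SE, and levels are CPM (counts scaled to equal library size, with TMM factors unless said otherwise) ± SD.

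The kn1 transcript followed genotype in every tissue. In leaf it reached 10.5 ± 0.778 CPM in homozygotes and 5.54 ± 0.797 CPM in heterozygotes, whereas the 2 wild-type libraries held 1 and 0 counts. The count ratio to wild type was 398 (95% interval 71.1 to 15772) in homozygotes and 214 (95% interval 37.9 to 8471) in heterozygotes. Homozygotes exceeded heterozygotes by 0.92 ± 0.16, adjusted p = 0.0053, a call that was lost without homozygote library 2 (adjusted p = 0.12). In kn1-e1 mutants kn1 fell but remained measurable. Tassels held 46.1 ± 10.9 CPM against 201 ± 12.4 CPM in siblings (-2.12 ± 0.12, adjusted p = 8.7e-07). Ears held 33.9 ± 0.140 CPM against 133 ± 6.37 CPM (-1.98 ± 0.06, adjusted p = 8.2e-10). In the SAM the values were 11.1 ± 1.38 CPM against 35.2 ± 2.79 CPM (-1.66 ± 0.13, adjusted p = 3.1e-05). No difference of this fall between tissues passed. Ear minus tassel was 0.13 ± 0.17 (adjusted p = 0.74), SAM minus tassel 0.46 ± 0.20 (adjusted p = 0.33) and SAM minus ear 0.34 ± 0.22 (adjusted p = 0.40).

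**Figure D1:**
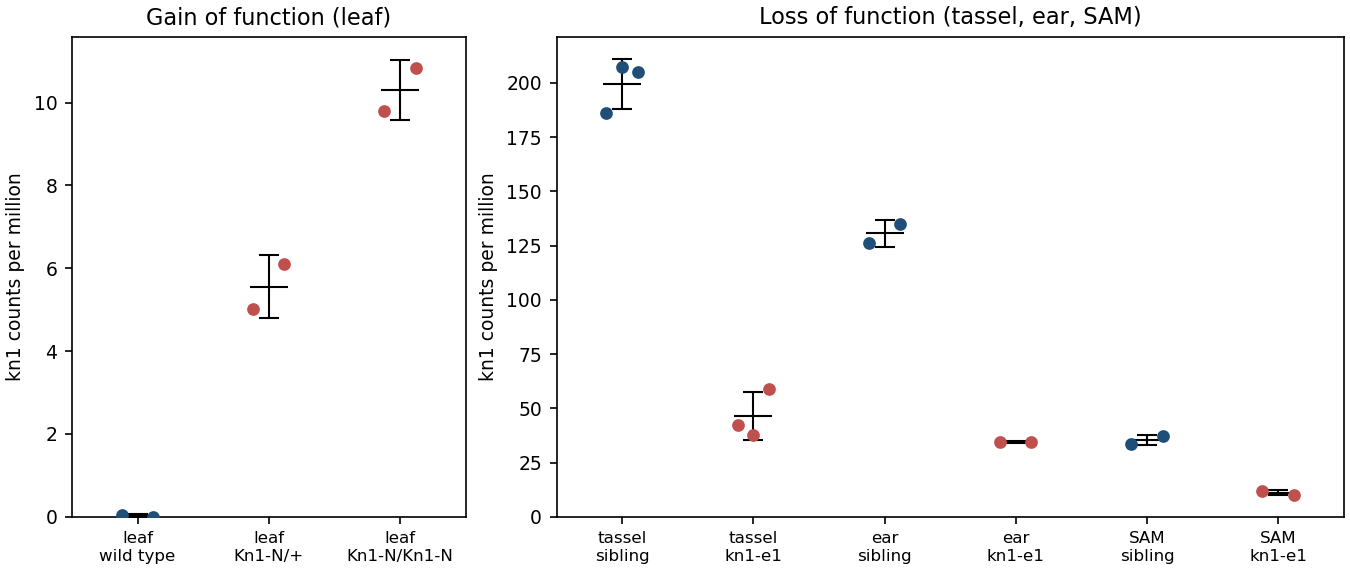
kn1 level in each library in CPM of the library total, with leaf genotypes in the left panel and tassel, ear and SAM groups in the right; points are libraries, the line is the group mean and bars are SD. Wild-type leaf libraries lie at 0.0513 and 0 CPM, and every kn1-e1 library lies below every sibling library of its tissue.

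In homozygous Kn1-N leaves, 3 of 5 KNOX and BELL genes and 9 of 17 growth-regulating factor genes rose, and 18 of 29 cell wall genes fell. Besides kn1, the KNOX genes lg3 (GRMZM2G087741) and lg4 (GRMZM2G094241) rose. lg3 went from 0.128 ± 0.106 to 5.32 ± 0.511 CPM (5.31 ± 0.37, adjusted p = 2.0e-06). lg4 had 2 counts in wild type, and its count ratio was 42.9 (95% interval 11.5 to 360.4) with adjusted p = 2.4e-05. Of 5 KNOX and BELL genes tested, these 3 rose and 0 fell (the same adjusted over the list alone, adjusted p = 0.00035, adjusted p = 0.66 with an estimated correlation). The list holds kn1 itself, which rose with the allele, so its adjusted p does not speak for the other members. In wild type kn1, lg3 and lg4 had 1, 5 and 2 counts, so they passed the low-count filter only through the mutant libraries. Such genes could hardly fall, so the 3 of 5 that rose and the 0 that fell are partly set by the filter. Growth-regulating factors and their partner GIF1 rose in 9 of 17 cases and fell in 0 (10 up adjusted over the list alone). Their median was 0.33 (adjusted p = 7.6e-05, adjusted p = 0.66 with an estimated correlation). GIF1 (GRMZM2G180246), a GRF-interacting coactivator, went from 31.2 to 72.1 CPM (1.21 ± 0.08, adjusted p = 1.6e-06). It lies 15 tested genes from kn1 in the reference order. GRF12 (GRMZM2G119359) changed by 0.91 ± 0.11, adjusted p = 0.00013, and GRF2 (GRMZM2G099862) by 0.70 ± 0.08, adjusted p = 0.00015. Among YABBY genes, which mark lateral organs, 5 of 8 rose and 1 fell (6 and 1 adjusted over the list alone, median 0.48, adjusted p = 0.0058, adjusted p = 0.66 with an estimated correlation). Among them was yabby15 (GRMZM2G529859) at 1.30 ± 0.07, adjusted p = 3.5e-07. HD-ZIP and other leaf polarity genes rose in 2 of 9 cases (5 adjusted over the list alone, median 0.20, adjusted p = 0.028, adjusted p = 0.66 with an estimated correlation).

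In homozygous leaves 21 of 35 ribosomal protein genes and 13 of 32 cell cycle genes also rose. Cytosolic ribosomal protein genes rose in 21 of 35 cases and fell in 0 (27 up adjusted over the list alone). Their median was 0.23 (adjusted p = 4.2e-07, adjusted p = 0.73 with an estimated correlation), with RPL10 (GRMZM2G087233) at 0.39 ± 0.06, adjusted p = 0.0011. Cell cycle and DNA replication genes rose in 13 of 32 cases and fell in 2 (16 and 2 adjusted over the list alone, median 0.18, adjusted p = 0.029, adjusted p = 0.73 with an estimated correlation). The kinase gene wee1 (GRMZM5G878541) changed by 0.49 ± 0.07, adjusted p = 0.00032 and the kinesin gene KIN8 (GRMZM2G132371) by 0.31 ± 0.06, adjusted p = 0.0020. Cell wall loosening and cellulose genes fell in 18 of 29 cases and rose in 0 (21 down adjusted over the list alone, median -0.47, adjusted p = 2.0e-07, adjusted p = 0.66 with an estimated correlation). The cellulose synthase genes CesA-4 (GRMZM2G424832) and CesA-2 (GRMZM2G027723) changed by -0.65 ± 0.06 and -0.62 ± 0.06 (adjusted p = 2.0e-05 and 3.5e-05), and the xyloglucan endotransglucosylase gene xth1 (GRMZM2G119783) by -2.26 ± 0.26, adjusted p = 8.7e-05. The aquaporin genes pip2c (GRMZM2G081192), PIP2-4 (GRMZM2G154628) and TIP2-1 (GRMZM2G027098) changed by -2.03 ± 0.15, -2.01 ± 0.15 and -2.30 ± 0.36 (adjusted p = 2.2e-06, 3.7e-06 and 0.00088). Myb20 (GRMZM2G150841) changed by -2.27 ± 0.32, adjusted p = 0.00044.

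Hormone and stress genes moved both ways in homozygous leaves. Auxin genes rose in 11 and fell in 7 of 46 cases (12 and 8 adjusted over the list alone, adjusted p = 0.40 for the list). The efflux carrier gene PIN1a (GRMZM2G098643) changed by 0.63 ± 0.07, adjusted p = 5.2e-05, and the conjugation enzyme gene GH3 (GRMZM2G378106) by 1.99 ± 0.27, adjusted p = 0.00035. Among inflorescence and meristem genes 4 rose and 2 fell of 25 (4 and 2 adjusted over the list alone, adjusted p = 0.61). BIF4 (GRMZM5G864847) changed by 1.95 ± 0.25, adjusted p = 0.00022 and the flowering regulator id1 (GRMZM2G011357) by -0.87 ± 0.12, adjusted p = 0.00038. The largest other increases included the silicon transporter gene Lsi1 (GRMZM2G028325) (3.22 ± 0.38, adjusted p = 1.0e-04) and the proteinase inhibitor gene MPI (GRMZM2G028393) (2.72 ± 0.39, adjusted p = 0.00049). Jasmonate genes rose in 2 and fell in 6 of 37 cases (the same numbers adjusted over the list alone, adjusted p = 0.63). Heat shock genes, listed as a sign of handling, rose in 8 and fell in 4 of 24 cases (9 and 4 adjusted over the list alone, adjusted p = 0.65). The chaperone gene Hsp70 (GRMZM2G310431) differed by 1.19 ± 0.23, adjusted p = 0.0038. Its call was lost without homozygote library 2 or wild-type library 1 (adjusted p = 0.068 and 0.059) and by DESeq2 (adjusted p = 0.098).

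In all, 4139 of 22071 genes tested passed in homozygous leaves against wild type by edgeR, 2022 up and 2117 down, and of these 190 rose and 422 fell at least 2-fold. The count was 1495 and 1061 without homozygote library 1 or 2 and 1507 and 2197 without wild-type library 1 or 2. DESeq2 called 2397 genes, and with library totals as the only scaling the split was 1528 up and 2586 down.

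**Figure D2:**
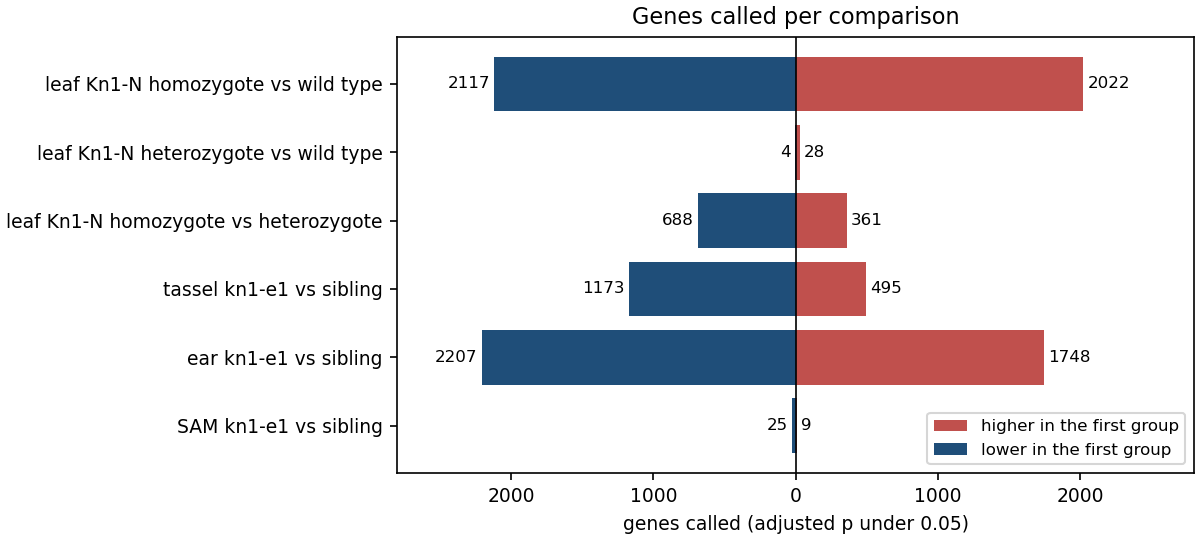
Number of genes called at adjusted p under 0.05 (edgeR) in each comparison, with bars for genes higher and genes lower in the first group named. Homozygous leaf had 4139 calls, ear 3955, heterozygous leaf 32 and SAM 34.

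Heterozygous leaves shared the KNOX gains but passed the test at few other genes. lg3 rose from 0.128 to 3.68 ± 0.266 CPM (4.77 ± 0.39, adjusted p = 6.4e-05). lg4 reached 2.08 ± 0.278 CPM with a count ratio of 40.1 (95% interval 10.8 to 336) and adjusted p = 0.00037. These and kn1 were the 3 of 5 KNOX and BELL genes that rose, and 0 fell (the same adjusted over the list alone, adjusted p = 4.7e-08, adjusted p = 0.66 with an estimated correlation). With kn1 itself in the list, this adjusted p too does not speak for the other members. Here too, kn1, lg3 and lg4 passed the low-count filter only through the mutant libraries, so these numbers are partly set by the filter. yabby15 rose by 0.91 ± 0.07, adjusted p = 6.4e-05. It was the 1 of 8 YABBY genes that passed (3 adjusted over the list alone, median 0.28, adjusted p = 0.0012, adjusted p = 0.66 with an estimated correlation). GIF1 rose by 0.63 ± 0.08, adjusted p = 0.0059 and Lsi1 by 2.71 ± 0.40, adjusted p = 0.014. Without wild-type library 1 or 2 neither passed, though GIF1 still changed by 0.62 and 0.64 and Lsi1 by 2.68 and 2.73. Cell wall genes had a median of -0.13 with 0 of 29 called (0 down adjusted over the list alone, adjusted p = 0.0024, adjusted p = 0.73 with an estimated correlation). The cell cycle list had a median of 0.07 with 0 of 32 called (2 up adjusted over the list alone, adjusted p = 0.025, adjusted p = 0.73 with an estimated correlation). The auxin list had a median of 0.05 with 0 of 46 called (4 up and 0 down adjusted over the list alone, adjusted p = 0.042, adjusted p = 0.66 with an estimated correlation). The 4 genes that fell had no name in the reference table and were named after their values were seen: GRMZM2G077015 (-0.84 ± 0.13), GRMZM2G045849 (-0.75 ± 0.12), GRMZM2G147849 (-0.39 ± 0.06) and GRMZM2G130173 (-1.05 ± 0.18). The test called 32 genes, 28 up and 4 down, with 1561 at an unadjusted p under 0.05. The count was 628 without heterozygote library 1, and 8 and 13 without wild-type library 1 or 2.

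Between homozygous and heterozygous leaves, 6 of 17 growth-regulating factor genes rose and 13 of 29 cell wall genes fell. No list was tested as a group in this comparison. GIF1 was higher in homozygotes (72.1 ± 1.33 CPM against 48.1 ± 5.67 CPM, 0.58 ± 0.08, adjusted p = 0.0010). Growth-regulating factors rose in 6 of 17 cases and fell in 0 (10 up adjusted over the list alone, median 0.35). Cell wall genes fell in 13 of 29 cases and rose in 0 (18 down adjusted over the list alone, median -0.32). Among them were CesA-4 (-0.55 ± 0.06, adjusted p = 0.00031), CesA-2 (-0.49 ± 0.06, adjusted p = 0.00073) and xth1 (-1.86 ± 0.27, adjusted p = 0.0016). Ribosomal protein genes rose in 3 of 35 cases (26 adjusted over the list alone), a number that was 0 with library totals as the only scaling. The aquaporin gene pip2c fell by 1.73 ± 0.15 and Myb20 fell by 2.02 ± 0.33 on the log2 scale (adjusted p = 5.5e-05 and 0.0039). The lipoxygenase gene lox12 (GRMZM2G106748) changed by -1.49 ± 0.17, adjusted p = 0.00035, whereas phytase2 (GRMZM2G043336) and phyS11 (GRMZM2G140101) changed by 1.86 ± 0.18 and 1.83 ± 0.21 (adjusted p = 0.00013 and 0.00031). Heat shock genes rose in 7 of 24 cases and fell in 0 (9 and 2 adjusted over the list alone), with a median of 0.02 that was -0.01 under library totals. The small heat shock genes hsp18f (GRMZM2G083810) and hsp22 (GRMZM2G007729) changed by 2.97 ± 0.52 and 2.35 ± 0.43 (adjusted p = 0.0060 and 0.0079). Neither passed without homozygote library 2 (adjusted p = 0.10 for each) or by DESeq2 (adjusted p = 0.18 for each). The test called 1049 genes, 361 up and 688 down. Without homozygote library 1 or 2 it called 253 and 166. Without heterozygote library 1 or 2 it called 559 and 3105, and DESeq2 called 612.

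Most genes called in heterozygotes were also called in homozygotes. Of the 32 genes called in heterozygotes, 31 were called in the same direction in homozygotes (27 up, 4 down), where lists drawn independently would share 2.95, and 29 changed more in homozygotes. Their median absolute log2 fold change was 0.87 in heterozygotes and 1.21 in homozygotes. Both comparisons used the same 2 wild-type libraries, which alone makes them alike. In 20 simulations of unchanged groups against those libraries, 0.35 genes were shared on average (0 to 2). The simulated groups had at most 10 calls each, so this number cannot show how much of the overlap the shared libraries produce. The correlation of log2 fold changes across genes was 0.656 (Spearman 0.626) against 0.501 (0.483 to 0.517; Spearman 0.459) in the simulations, with a covariance of 0.0855 against 0.0175. Over all genes 73.8% had the same sign in both comparisons against 66.7% in the simulations. Genes are not independent replicates.

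In kn1-e1 tassels, 8 of 22 SBP-box genes rose, while 12 of 36 genes of the jasmonate list, 5 of 7 YABBY genes and 7 of 22 MADS-box genes fell. SBP-box genes rose in 8 of 22 cases and fell in 0 (10 and 1 adjusted over the list alone). Their median was 0.16 (adjusted p = 9.6e-06, adjusted p = 0.66 with an estimated correlation). ub2 (GRMZM2G160917) and ub3 (GRMZM2G460544) went from 40.3 to 72.4 CPM (0.85 ± 0.05, adjusted p = 1.8e-06) and from 54.7 to 94.8 CPM (0.79 ± 0.06, adjusted p = 9.1e-06). Further SBP-box increases were sbp6 (GRMZM2G307588) (0.71 ± 0.05, adjusted p = 6.8e-06), sbp2 (GRMZM2G168229) (1.53 ± 0.20, adjusted p = 0.00051) and the ligule gene lg1 (GRMZM2G036297) (0.91 ± 0.13, adjusted p = 0.0011). Across the inflorescence and meristem list 5 of 39 rose and 7 fell (9 and 8 adjusted over the list alone, adjusted p = 0.84). The HD-ZIP gene gt1 (GRMZM2G005624) fell by 1.48 ± 0.18 on the log2 scale (adjusted p = 0.00030). Of 10 KNOX and BELL genes 1 rose and 2 fell (the same numbers adjusted over the list alone, adjusted p = 0.65 for the list). gnarley1 (GRMZM2G452178) rose (0.52 ± 0.05, adjusted p = 6.4e-05), and beside kn1 knox8 (GRMZM2G135447) fell (-0.31 ± 0.08, adjusted p = 0.041). knox8 did not pass without kn1-e1 library 2 or 3 (adjusted p = 0.083 and 0.076), without sibling library 1, 2 or 3 (adjusted p = 0.11, 0.18 and 0.068), or by DESeq2 (adjusted p = 0.094). YABBY genes fell in 5 of 7 cases and rose in 0 (the same numbers adjusted over the list alone, median -0.43, adjusted p = 0.0012, adjusted p = 0.71 with an estimated correlation). They included yabby15 (-0.42 ± 0.06, adjusted p = 0.00063) and yab14 (GRMZM2G005353) (-0.63 ± 0.11, adjusted p = 0.0029).

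Genes of the jasmonate list, which takes in lipoxygenase genes whatever their product, fell in 12 of 36 cases in kn1-e1 tassels and rose in 0 (the same numbers adjusted over the list alone, median -0.24, adjusted p = 1.5e-05, adjusted p = 0.71 with an estimated correlation). Lipoxygenase genes were among them. lox6 (GRMZM2G040095) held 31.0 ± 2.88 CPM against 78.0 ± 3.99 CPM (adjusted p = 5.9e-07). Further decreases were lox10 (GRMZM2G015419) (-1.01 ± 0.05, adjusted p = 8.7e-07), lox5 (GRMZM2G102760) (-0.97 ± 0.06, adjusted p = 1.8e-06) and lox11 (GRMZM2G009479) (-0.87 ± 0.11, adjusted p = 0.00053). MADS-box genes rose in 3 and fell in 7 of 22 cases (4 and 9 adjusted over the list alone, adjusted p = 0.33). MADS7 (GRMZM2G099522) and MADS5 (GRMZM2G102161) changed by -2.75 ± 0.29 and -1.61 ± 0.10 (adjusted p = 0.00011 and 1.8e-06), whereas AGAMOUS (GRMZM2G359952) rose by 1.21 ± 0.14, adjusted p = 0.00024. Cell wall genes rose in 1 and fell in 6 of 25 cases (2 and 12 adjusted over the list alone, median -0.17, adjusted p = 0.0012, adjusted p = 0.73 with an estimated correlation). The expansin genes expB2 (GRMZM2G021621) and expB8 (GRMZM2G013002) changed by -0.53 ± 0.08 and -0.38 ± 0.06 (adjusted p = 0.00096 and 0.0018). Ethylene genes rose in 1 and fell in 6 of 28 cases (1 and 9 adjusted over the list alone, adjusted p = 0.0054, adjusted p = 0.66 with an estimated correlation). Lignin genes fell in 4 of 14 (7 adjusted over the list alone, adjusted p = 0.0063, adjusted p = 0.71 with an estimated correlation). Auxin genes rose in 3 and fell in 4 of 45 cases (4 and 5 adjusted over the list alone, adjusted p = 0.50). Among them were AUX35 (GRMZM2G167794) (-0.92 ± 0.10, adjusted p = 0.00020) and the auxin response factor gene ARF28 (GRMZM2G006042) (0.22 ± 0.03, adjusted p = 0.0019). Large decreases outside these lists included the benzoxazinoid synthesis gene bx1 (GRMZM2G085381) (1.10 ± 0.656 CPM against 8.77 ± 1.51 CPM, adjusted p = 3.8e-05) and AGA3a (GRMZM2G050177) (-1.97 ± 0.16, adjusted p = 1.5e-05). The alcohol dehydrogenase gene adh1 (GRMZM2G442658), a neighbour of kn1, held 187 ± 14.6 CPM against 671 ± 155 CPM (adjusted p = 6.1e-06).

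The tassel test called 1668 of 21117 genes, 495 up and 1173 down, and of these 26 rose and 255 fell at least 2-fold. Mutant tassels measured 2 to 3 mm and sibling tassels 4 to 5.5 mm, so length and genotype differed together. The count was 1009, 884 and 1013 without sibling library 1, 2 or 3.

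In kn1-e1 ears, 19 of 31 MADS-box genes, 8 of 8 YABBY genes and 29 of 35 ribosomal protein genes fell, and 6 of 12 photosynthesis genes rose. MADS-box genes fell in 19 of 31 cases and rose in 2 (20 and 2 adjusted over the list alone). Their median was -0.45 (adjusted p = 4.7e-08, adjusted p = 0.66 with an estimated correlation). zmm6 (GRMZM2G159397) went from 53.4 ± 4.32 to 11.9 ± 0.628 CPM (-2.17 ± 0.09, adjusted p = 5.9e-09). MADS5 changed by -1.78 ± 0.07, adjusted p = 5.9e-09. zmm27 (GRMZM2G129034), zmm29 (GRMZM2G152862) and zag2 (GRMZM2G160687) changed by -1.51 ± 0.09, -2.86 ± 0.32 and -2.83 ± 0.18 (adjusted p = 1.7e-07, 6.4e-05 and 4.4e-07). YABBY genes fell in 8 of 8 cases (the same number adjusted over the list alone, median -0.55, adjusted p = 2.2e-06, adjusted p = 0.71 with an estimated correlation), among them yab14 (-0.70 ± 0.06, adjusted p = 1.2e-05) and yabby15 (-0.44 ± 0.06, adjusted p = 0.00023). Of 10 KNOX and BELL genes 1 rose and 3 fell (the same numbers adjusted over the list alone, adjusted p = 0.22). Beside kn1, lg4 fell (-0.55 ± 0.08, adjusted p = 0.00041), and so did knox8 (-0.37 ± 0.07, adjusted p = 0.0037, or adjusted p = 0.10 without sibling library 1). The inflorescence and meristem list had 7 up and 12 down of 38 (8 and 15 adjusted over the list alone, adjusted p = 0.076). In it the bZIP gene lg2 (GRMZM2G060216) went from 13.3 to 5.01 CPM, and the receptor-like gene fea3 (GRMZM2G166524) fell by 0.64 ± 0.07 on the log2 scale (adjusted p = 3.6e-05 and 3.9e-05), while ub2 rose by 0.61 ± 0.07, adjusted p = 7.7e-05. SBP-box genes rose in 7 and fell in 1 of 21 cases (8 and 2 adjusted over the list alone, adjusted p = 0.33). Their median was -0.0026 (0.05 under library totals) and their mean 0.12.

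Ribosomal protein genes fell in 29 of 35 cases in kn1-e1 ears and rose in 1 (32 and 1 adjusted over the list alone, median -0.33, adjusted p = 1.1e-11, adjusted p = 0.66 with an estimated correlation). rps24 (GRMZM2G091383), RPL10 and rps28 (GRMZM2G030293) changed by -0.56 ± 0.06, -0.45 ± 0.05 and -0.42 ± 0.05 (adjusted p = 3.9e-05, 5.8e-05 and 0.00019). Histone genes fell in 11 of 12 cases (the same number adjusted over the list alone, median -0.38, adjusted p = 6.8e-06, adjusted p = 0.66 with an estimated correlation). Cell cycle and DNA replication genes fell in 17 of 31 cases, or 11 with library totals as the only scaling (19 adjusted over the list alone, median -0.19, adjusted p = 1.5e-05, adjusted p = 0.73 with an estimated correlation). They included cyclin9 (GRMZM2G017081) (-0.41 ± 0.06, adjusted p = 0.00072), the replication clamp gene pcna2 (GRMZM2G108712) (-0.36 ± 0.06, adjusted p = 0.00084) and cycD1 (GRMZM2G006721) (-0.49 ± 0.08, adjusted p = 0.00093). Cuticle and wax genes fell in 8 of 16 (10 adjusted over the list alone, median -0.37, adjusted p = 0.00035, adjusted p = 0.73 with an estimated correlation). Growth-regulating factors fell in 2 of 17 (0 adjusted over the list alone and 0 under library totals, adjusted p = 0.035, adjusted p = 0.73 with an estimated correlation). Photosynthesis genes rose in 6 of 12 cases and fell in 1 (8 and 1 adjusted over the list alone, median 1.15, adjusted p = 0.00010, adjusted p = 0.66 with an estimated correlation), from low levels. psb29 (GRMZM2G033885) went from 1.35 to 7.52 CPM (2.46 ± 0.20, adjusted p = 5.2e-06) and the light-harvesting gene lhcb6 (GRMZM2G092427) from 0.561 to 2.78 CPM (2.29 ± 0.31, adjusted p = 0.00028).

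Auxin genes in kn1-e1 ears rose in 4 and fell in 10 of 47 cases (4 and 11 adjusted over the list alone, adjusted p = 0.11). The response factor gene ARF2 (GRMZM2G153233) changed by -0.63 ± 0.09, adjusted p = 0.00034 and ARF11 (GRMZM2G056120) by -0.44 ± 0.06, adjusted p = 0.00041. Jasmonate genes rose in 5 and fell in 9 of 31 cases (the same numbers adjusted over the list alone, adjusted p = 0.51). lox1 (GRMZM2G156861) and lox11 changed by -0.80 ± 0.07 and -0.88 ± 0.10 (adjusted p = 5.7e-06 and 7.0e-05). Heat shock genes rose in 3 and fell in 2 of 21 cases in ear (5 and 3 adjusted over the list alone, adjusted p = 0.63) and rose in 1 and fell in 2 of 20 in tassel (2 and 2, adjusted p = 0.51). In ear, Hsp70 held 94.3 ± 55.5 CPM against 29.9 ± 5.33 CPM (1.65 ± 0.28, adjusted p = 0.0012), and hsp18f changed by 1.31 ± 0.20, adjusted p = 0.00055. These 2 genes were picked after their values in ear were seen. Other large increases included MPI (4.27 ± 0.39, adjusted p = 1.3e-05), m21 (GRMZM5G814279) (3.43 ± 0.13, adjusted p = 5.0e-09) and LOB15 (GRMZM2G060544) (2.65 ± 0.22, adjusted p = 6.6e-06). Other large decreases included m1 (GRMZM2G010669) (-3.47 ± 0.24, adjusted p = 9.6e-07), EDS (GRMZM2G010356) (-2.47 ± 0.31, adjusted p = 0.00017) and adh1 (-2.21 ± 0.17, adjusted p = 2.5e-06). The ear test called 3955 of 21281 genes, 1748 up and 2207 down, and of these 277 rose and 234 fell at least 2-fold. Mutant ears measured 4 to 5 mm and sibling ears 7 to 8 mm, so length again differed with genotype. The count was 1313 and 1167 without sibling library 1 or 2. DESeq2 called 1846, and with library totals as the only scaling the split was 2668 up and 1541 down.

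**Figure D3:**
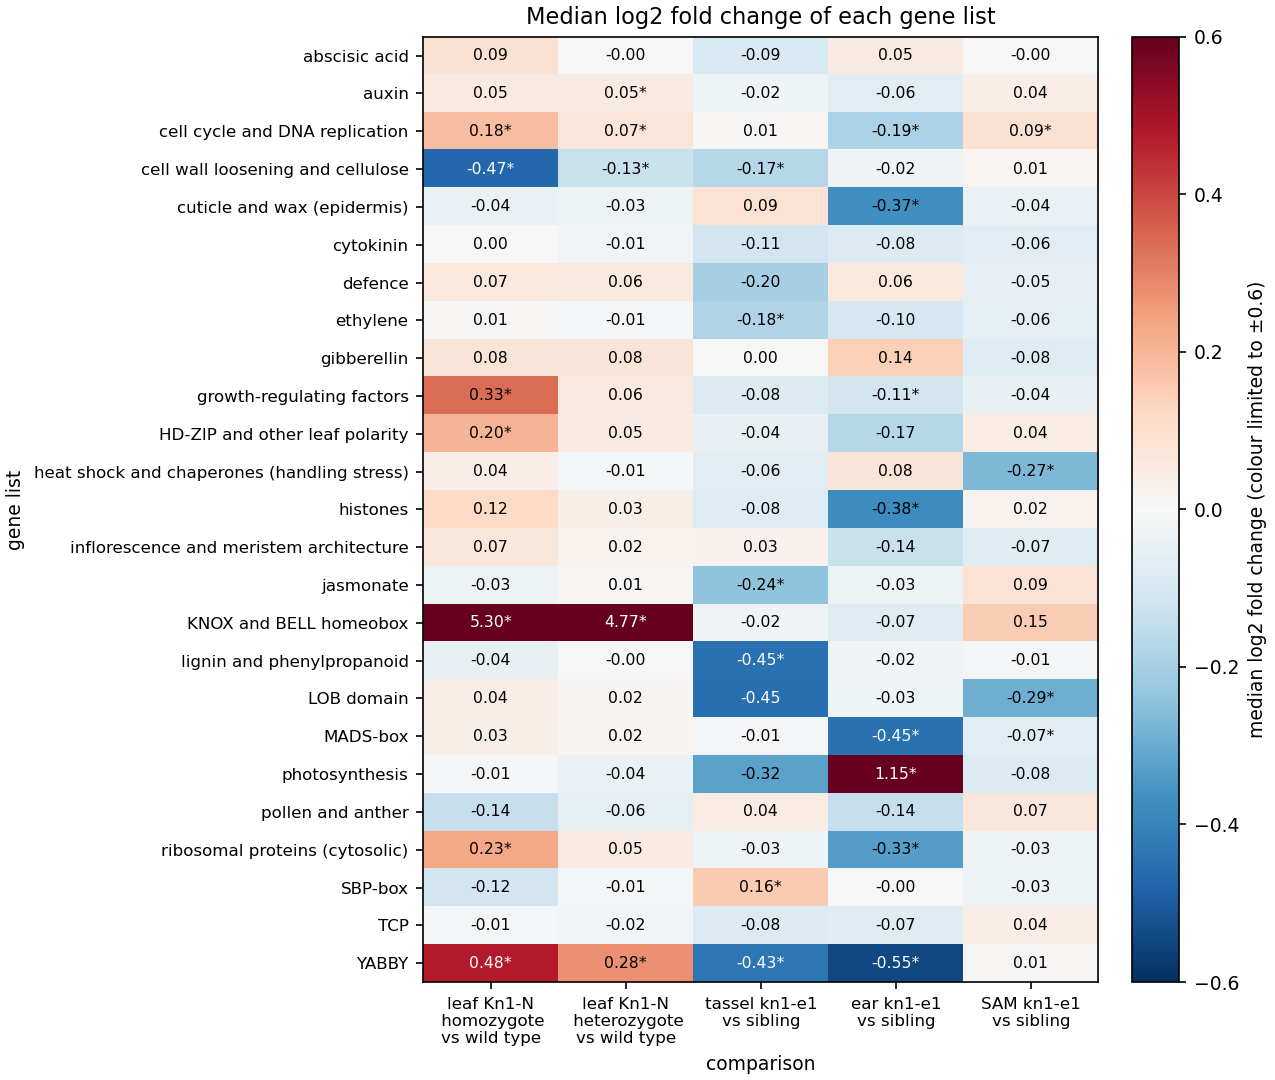
Median log2 fold change of each gene list (vertical axis) in the comparisons with a control (horizontal axis), with colour limited to ±0.6 and an asterisk where camera with a preset correlation gave an adjusted p under 0.05. Ribosomal protein genes have a median of 0.23 in homozygous leaf and -0.33 in ear, and none of the 30 asterisks holds with an estimated correlation. The test with an estimated correlation had little power with so few libraries.

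In the kn1-e1 SAM 34 genes passed, among them adh1 and 5 of 22 heat shock genes, which fell. The adh1 transcript went from 178 ± 27.2 to 31.6 ± 8.85 CPM (-2.49 ± 0.17, adjusted p = 1.2e-05). The lipoxygenase genes lox1 and lox10 rose by 1.43 ± 0.15 and 1.52 ± 0.21 (adjusted p = 0.00068 and 0.0068), the 2 of 31 genes of the jasmonate list that passed. The same number passed adjusted over the list alone (median 0.09, adjusted p = 0.11). EDS rose by 2.75 ± 0.28, adjusted p = 0.00052, and the benzoxazinoid gene BX3 (GRMZM2G167549) by 0.67 ± 0.11, adjusted p = 0.026. BX3 did not pass without kn1-e1 library 1 or 2 (adjusted p = 0.060 and 0.19). Heat shock genes fell in 5 of 22 cases and rose in 0 (8 down adjusted over the list alone, median -0.27, adjusted p = 5.1e-07, adjusted p = 0.66 with an estimated correlation). Hsp70 held 27.4 ± 1.11 CPM against 79.5 ± 17.04 CPM (-1.54 ± 0.14, adjusted p = 0.00013), and hsp1 (GRMZM5G802801) changed by -1.42 ± 0.20, adjusted p = 0.0072. hsp22 held 1.82 ± 0.464 CPM against 11.8 ± 7.38 CPM (adjusted p = 0.0084), but did not pass by DESeq2 (adjusted p = 0.10) or with all 20 libraries in 1 fit (adjusted p = 0.052). hsp18f changed by -1.62 ± 0.26, adjusted p = 0.023, and did not pass in these settings either (adjusted p = 1.0 and 0.057). The 2 sibling libraries, in which these genes spread widely, differed more than any other replicate pair (chi-square per degree of freedom 12.3 against 1.83 to 5.50). MADS-box genes fell in 1 of 14 cases (2 adjusted over the list alone, adjusted p = 0.011, adjusted p = 0.66 with an estimated correlation). This was ZAGL1 (GRMZM2G026223) at -0.62 ± 0.10, adjusted p = 0.027, which did not pass without kn1-e1 library 1 or 2 (adjusted p = 0.12 and 0.50). LOB domain genes had a median of -0.29 with 0 of 5 called (adjusted p = 0.011, adjusted p = 0.73 with an estimated correlation). Cell cycle genes had a median of 0.09 with 0 of 31 called (adjusted p = 0.042, adjusted p = 0.78 with an estimated correlation). The test called 34 of 20748 genes, 9 up and 25 down, with 981 at an unadjusted p under 0.05. The count was 55 without kn1-e1 library 2, and 110 and 1746 without sibling library 1 or 2.

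The mutant changes in tassel and ear overlapped. In the same direction, 146 genes rose in both (40.5 for independent lists, Fisher exact p = 4.9e-45) and 255 fell in both (113, Fisher exact p = 1.8e-37), 401 of the 591 called in both. ub2 rose in both, and MADS5, yabby15, yab14, lox11, knox8, kn1 and adh1 fell in both. DESeq2 calls shared 203 genes. Tassel and SAM shared 12 decreases (1.22, Fisher exact p = 4.1e-10) and 1 increase, GRMZM2G384897 (0.213, Fisher exact p = 0.19), 13 of 19 called in both, so 6 moved oppositely. Ear and SAM shared 12 decreases (2.25, Fisher exact p = 3.2e-07) and 3 increases, GRMZM2G384897, BX3 and GRMZM2G117281 (0.733, Fisher exact p = 0.031), 15 of 21 called in both, so 6 moved oppositely. At an adjusted p under 0.01 ear and SAM shared 0 increases (0.136 for independent lists). These tests were two-sided, no library was shared between tissues, and genes are not independent replicates. In all 3 tissues 12 of 19933 genes were called in the same direction, 11 down and 1 up. They were kn1, adh1, GRMZM2G028500, GRMZM2G047456, GRMZM2G179490, GRMZM2G401331, GRMZM2G024958, GRMZM2G133169, GRMZM2G157727, GRMZM2G464782 and GRMZM5G877929, which fell, and GRMZM2G384897, which rose. Those without a name were chosen after their values were seen. The 6 of these 12 with a place in the gene order, kn1 among them, all lie on the chromosome of kn1. Besides kn1 itself, 4 of them lie within 50 placed genes of kn1, and the other 6 of the 12 have no place.

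Some genes moved in opposite directions in homozygous Kn1-N leaf and in kn1-e1 tissues. Tassel and ear length differed with genotype, so an effect of kn1 cannot be told from one of stage there. yabby15 rose in homozygous leaf (1.30 ± 0.07) and fell in kn1-e1 tassel (-0.42 ± 0.06) and ear (-0.44 ± 0.06). lox11 did likewise, with 0.71 ± 0.08, adjusted p = 6.4e-05 in leaf, -0.87 ± 0.11 in tassel and -0.88 ± 0.10 in ear. yab14 rose in leaf by 0.66 ± 0.14, adjusted p = 0.0055 and fell in tassel and ear. Its leaf call was lost without homozygote library 1 or wild-type library 1 (adjusted p = 0.074 and 0.085). With kn1 these were among 7 named genes called in opposite directions in homozygous leaf and in at least 2 kn1-e1 tissues. Between leaf and ear, 539 genes rose in leaf and fell in ear (200 for independent lists, Fisher exact p = 1.0e-117), and 133 did the reverse (138, Fisher exact p = 0.71). In the same direction 152 rose in both (153, Fisher exact p = 1.0) and 270 fell in both (181, Fisher exact p = 3.9e-12), so that 672 of 1094 genes called in both moved oppositely. Between leaf and tassel, 166 of 449 moved oppositely, with 133 up in leaf and down in tassel (101, Fisher exact p = 0.0010) and 33 the reverse (38.1, Fisher exact p = 0.44). The other 283 moved the same way, 84 up (43.0, Fisher exact p = 1.8e-09) and 199 down (89.4, Fisher exact p = 4.4e-28). Between leaf and SAM, 8 of 18 moved oppositely, all up in leaf and down in SAM (2.04, Fisher exact p = 0.00050), and 10 moved the same way, 4 up (0.776, Fisher exact p = 0.0045) and 6 down (1.72, Fisher exact p = 0.0056). DESeq2 calls gave 321 opposite genes for ear and 97 for tassel. The overlaps were not run with library totals as the only scaling. That scaling split homozygous leaf into 1528 up and 2586 down and ear into 2668 up and 1541 down. The excess for SAM was lost with DESeq2 (2 genes up in leaf and down in SAM against 1.203, Fisher exact p = 0.34) and with all 20 libraries in 1 fit (4 against 2.88, Fisher exact p = 0.53). Of the SAM genes moving the same way, the excess of decreases was lost with all 20 libraries in 1 fit (7 against 3.54, Fisher exact p = 0.084) and that of increases at an adjusted p under 0.01 (0 against 0.135, Fisher exact p = 1.0). For ear, genes up in both exceeded independent lists with DESeq2 (44 against 32.7, Fisher exact p = 0.044) and at an adjusted p under 0.01 (35 against 22.1, Fisher exact p = 0.0079). For tassel, genes down in leaf and up in tassel did so at an adjusted p under 0.01 (12 against 5.88, Fisher exact p = 0.018).

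Called genes were more frequent beside kn1 in the kn1-e1 comparisons. Among the 50 tested genes placed on each side of kn1 in the gene order of Zm-B73-REFERENCE-NAM-5.0, 38 of 100 were called in tassel (13 up, 25 down) against 8.59% of other placed genes (odds ratio 6.52, 95% interval 4.22 to 9.96). In ear 40 of 100 were called (15 up, 25 down) against 19.6% (odds ratio 2.74, 1.79 to 4.17). In the SAM 4 of 100 were called against 0.130% (odds ratio 31.97, 7.73 to 99.5): adh1, GRMZM2G028500, GRMZM2G179490 and GRMZM2G401331. In heterozygous leaf 2 of 100 were called, GIF1 and GRMZM2G147849, against 0.143% (odds ratio 14.3, 1.60 to 59.6). GIF1 did not pass without wild-type library 1 or 2, though its log2 fold change was still 0.62 and 0.64. In homozygous leaf 28 of 100 were called (6 up, 22 down) against 20.5% (odds ratio 1.504, 0.934 to 2.36), an interval that includes 1. Without these genes the counts were 4107 in homozygous leaf, 30 in heterozygous leaf, 1615 in tassel, 3903 in ear and 28 in SAM. Unnamed genes and this setting were chosen after the values were seen.

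**Figure D4:**
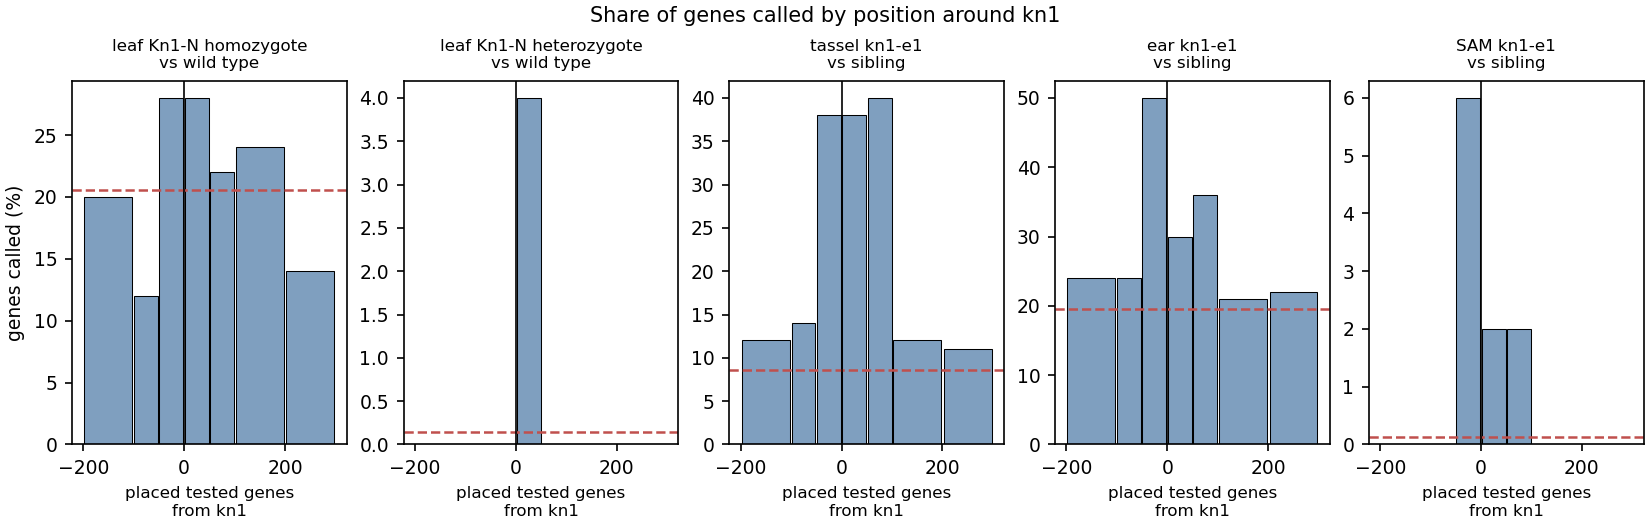
Share of tested, placed genes called (vertical axis, percent) by their position in gene order relative to kn1 (horizontal axis, genes), for the comparisons with a control; the dashed line is the share of all other placed genes. In tassel 38 of the 100 nearest genes were called against 8.59% elsewhere.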

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

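The test for leaf tissue in the SAM sibling libraries was chosen only after the result was seen. Differences between kn1-e1 and siblings that varied by tissue are given first, each tested in 1 edgeR fit as the difference of log2 fold changes. Primordium length differed with genotype in tassel and ear, whereas the labels give no size difference in the SAM. A mutant effect that varies by tissue therefore cannot be told from unequal differences in stage.

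Between tassel and ear the mutant effect differed for 1169 of 22387 genes (668 higher and 501 lower in ear). Among the named genes with opposite or unequal effects, ear minus tassel was 3.46 ± 0.23 for m21 (adjusted p = 5.0e-07), 1.3999 ± 0.1118 for lox6 (adjusted p = 1.1e-06), 3.30 ± 0.31 for psb29 (adjusted p = 5.0e-06), -2.85 ± 0.27 for AGAMOUS (adjusted p = 2.0e-05) and 1.98 ± 0.22 for gt1 (adjusted p = 4.6e-05). The count was 755 without kn1-e1 tassel library 3, 767 and 619 without sibling tassel library 1 or 3, 373 without kn1-e1 ear library 1, and 394 and 384 without sibling ear library 1 or 2. With library totals as the only scaling the split was 861 and 280.

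Between tassel and SAM the effect differed for 265 genes (183 higher and 82 lower in SAM). SAM minus tassel was 2.54 ± 0.19 for lox10 (adjusted p = 1.1e-06), 2.51 ± 0.22 for lox1 (adjusted p = 5.5e-06), 1.07 ± 0.11 for lox5 (adjusted p = 4.8e-05), 1.25 ± 0.11 for BX3 (adjusted p = 5.5e-06) and -1.15 ± 0.12 for ub3 (adjusted p = 3.5e-05). The count was 174 and 153 without sibling tassel library 1 or 2, 114 and 105 without kn1-e1 SAM library 1 or 2, and 1644 without sibling SAM library 2. Under library totals the split was 145 and 117.

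Between ear and SAM the effect differed for 1224 genes (750 higher and 474 lower in SAM). SAM minus ear was 5.24 ± 0.47 for EDS (adjusted p = 1.1e-05), -3.60 ± 0.18 for m21 (adjusted p = 3.2e-09), -3.16 ± 0.39 for Hsp70 (adjusted p = 0.00027), 2.25 ± 0.25 for lox1 (adjusted p = 0.00011) and 1.00 ± 0.14 for lox11 (adjusted p = 0.0012). The count was 378 without kn1-e1 ear library 1, 415 and 381 without sibling ear library 1 or 2, 487 and 656 without kn1-e1 SAM library 1 or 2, and 2058 and 2191 without sibling SAM library 1 or 2. Under library totals the split turned to 347 and 863.

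The changes that tassel and ear share may reflect the shorter primordia of the mutants, since length and genotype differed together in both tissues. In the SAM, where the labels give no size difference, 182 of the 374 shared genes tested there had the same sign (48.7%, 95% interval 43.5 to 53.9), which is what a cause by stage alone predicts. Without kn1 and the genes within 100 of it the share was 44.7% (39.3 to 50.1). An effect of kn1 limited to inflorescences, or changes too small to show in the SAM, predict the same, and neither was tested. These intervals take genes as independent, though all signs come from the same SAM libraries. As to chance in the tassel itself, 1 of the 10 splits of the 6 libraries, the real one, gave 1668 genes and the highest other split 0; 10 splits are too few for a share under 0.05.

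The 2 sibling SAM libraries stood further apart than any other replicate pair (chi-square per degree of freedom 12.3 against 1.83 to 5.50), and the SAM count was 1746 without sibling library 2. More young leaf tissue in one pool could be a cause: 310 genes at least 8-fold higher in wild-type leaf than in tassel and ear siblings had a median log2 difference of 0.0813 (0.0381 to 0.131) between library 1 and library 2. The test was set to count for the explanation at a median over 0.2 and against it at an interval within -0.1 to 0.1. The result met neither, so it cannot tell, and it sets only 2 single libraries side by side. Single genes of at least 1 CPM had an SD of 0.285 between these libraries, which is not the error of a median of 310 genes. A mixture of wild-type and heterozygous plants among the siblings, which the design allows, was not tested.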

How the results depend on the processing

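The crossed replicate block in SAM and the counts without the genes beside kn1 were chosen only after the result was seen. None of the named-gene values compared reversed under the alternatives run. List calls were compared by adjusted p alone, and 42 of 90 stayed under 0.05. Their direction was not compared. List medians near 0 changed sign with other scaling, as for SBP-box genes in ear. Of 134 counts under other settings 86 stayed within 1.5 times, and of 54 counts with a library left out 17 did. Of 1923 values of the genes that the rule named, 1808 kept their direction and side of the threshold; 7 of 32 genes lost their call at least once in homozygous leaf, 2 of 6 in heterozygous leaf, 18 of 27 between these, 3 of 30 in tassel, 2 of 34 in ear and 4 of 11 in SAM. For the counts below, the cause was not tested, except that a stricter threshold gives fewer calls by construction. Leaving out a library gave fewer calls in some cases and more in others.

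With 1 library left out, the count ranged from 1061 to 2197 in homozygous leaf, 8 to 628 in heterozygous leaf, 166 to 3105 between these, 884 to 2228 in tassel, 1167 to 5898 in ear and 48 to 1746 in SAM, and from 373 to 1179, 105 to 1644 and 378 to 2191 for tassel against ear, tassel against SAM and ear against SAM; the lone library of a group was assumed to vary like the other groups. DESeq2 gave 2397 in homozygous leaf, 612 between homozygotes and heterozygotes and 1846 in ear. At an adjusted p under 0.01 the counts were 1701, 14 and 346 for the leaf comparisons, 760 in tassel, 1899 in ear, 17 in SAM, and 335, 103 and 300 for the differences between tissues. Without a filter the SAM count was 111 and those differences 2151, 857 and 1970. All 20 libraries in 1 fit gave 64 in SAM. A replicate block gave 72 in SAM and 776, 170 and 633 for the differences. A crossed block, which pairs unlike replicate numbers, gave 105 in SAM, so the gain does not speak for pairing. With only the genotypes compared, homozygous leaf had 5737 calls.

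Shared calls in the same direction of tassel and ear were 203 by DESeq2 and 155 at 0.01; those of tassel and SAM were 20 without a filter and 8 at 0.01, and those of ear and SAM 29 without a filter, 27 with a block and 8 at 0.01. Genes opposite in leaf and tassel were 97 by DESeq2 and 65 at 0.01, and genes alike 144 and 65. For leaf and ear, opposite genes were 321 by DESeq2, 413 with all libraries and 161 at 0.01, and genes alike 136 by DESeq2 and 112 at 0.01. For leaf and SAM, opposite genes were 2 by DESeq2, 16 without a filter, 4 with all libraries and 3 at 0.01, and genes alike 24 without a filter, 20 with a block and 3 at 0.01. Homozygous and heterozygous leaf shared 13 at 0.01. Of 125 list tests camera called 30 with the preset correlation and 0 with an estimated one. The latter had only the 2 to 4 residual degrees of freedom of the fits and so little power. A replicate block left 29 calls by camera with the preset correlation, and fry called 19 (74 in either direction). In SAM 73.1% of simulated 1.5-fold changes were recovered, the lowest share. The simulation changed only better expressed genes and left out extra spread of single genes or libraries, so the real share may be lower. Intervals and ratios for genes of few counts cover counting error only.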

Other observations

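The count of calls per window of genes, the shared direction beside kn1 and the comparison of single unnamed genes were chosen only after the result was seen. Camera called none of the hormone and other lists not described so far that had at least 5 tested members. The brassinosteroid, circadian clock and vascular lists had fewer and were not tested by camera. Lists hold only genes with a matching symbol in the reference table, so few calls in a list do not speak for its whole pathway. For comparison, 18.8% of all genes tested were called in homozygous leaf. Cytokinin genes were 4 up and 0 down of 24 in homozygous leaf (3 and 3 under library totals), 1 up and 0 down of 26 in tassel and 2 up and 3 down of 26 in ear. Gibberellin genes were 1 up and 0 down of 8 in homozygous leaf, 1 up and 1 down of 8 in tassel and 1 up and 1 down of 7 in ear, and abscisic acid genes 0 up and 2 down of 12, 1 up and 1 down of 11 and 1 up and 0 down of 12. TCP genes were 0 up and 0 down of 7 in homozygous leaf, 0 up and 1 down of 6 in tassel and 0 up and 2 down of 8 in ear. Defence genes were 3 up and 2 down of 16, 0 up and 4 down of 17 and 3 up and 3 down of 16, and pollen and anther genes 1 up and 3 down of 6, 0 up and 0 down of 6 and 1 up and 1 down of 6. Of 3 brassinosteroid genes 1 fell in homozygous leaf and 1 in tassel, and of 3 circadian clock genes and 3 vascular genes 0 were called. In heterozygous leaf and in SAM 0 genes of these lists were called.

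A pair of unnamed genes fell with kn1 in kn1-e1 tassel, ear and SAM and rose in homozygous Kn1-N leaf. In heterozygous leaf only GRMZM2G157727 was called. GRMZM2G157727 fell in kn1-e1 tassel (-1.31 ± 0.07), ear (-1.80 ± 0.07) and SAM (-2.48 ± 0.15; adjusted p = 6.2e-06) and rose in homozygous leaf (0.81 ± 0.09; adjusted p = 7.4e-05) and heterozygous leaf (0.59 ± 0.09; adjusted p = 0.019). GRMZM2G464782 fell in tassel (-2.12 ± 0.07), ear (-2.10 ± 0.13) and SAM (-2.49 ± 0.21; adjusted p = 6.1e-05) and rose in homozygous leaf (0.24 ± 0.07; adjusted p = 0.037), with 0.05 ± 0.07 in heterozygous leaf (adjusted p = 0.92). Neither has a place in the gene order used here.

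Other genes fell with both alleles. GRMZM2G179490, GRMZM2G028500, GRMZM2G401331 and adh1, all beside kn1, fell in all 3 kn1-e1 tissues and also in homozygous Kn1-N leaf, where kn1 itself rose. In homozygous leaf GRMZM2G179490 held 0.0859 against 3.09 CPM (adjusted p = 1.5e-05). GRMZM2G028500 changed there by -1.62 ± 0.17 (adjusted p = 4.3e-05), GRMZM2G401331 by -1.005 ± 0.272 (adjusted p = 0.022) and adh1 by -0.53 ± 0.06 (adjusted p = 6.7e-05). In ear GRMZM2G179490 was at 0 counts in both mutant libraries and at 2.24 ± 0.0290 CPM in siblings.

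The calls beside kn1 may come from a chromosome segment that arrived with the mutant allele from another background: the odds of a call among the 100 nearest genes were raised in tassel (odds ratio 6.52), ear (2.74) and SAM (31.97), as a linked segment predicts, and cannot be told from 1 in homozygous leaf (1.504, 0.934 to 2.36). In heterozygous leaf the ratio was 14.3 but rests on 2 genes. Of these, GIF1 did not pass without wild-type library 1 or 2, though its log2 fold change was still 0.62 and 0.64. In windows of 100 placed genes, with kn1 itself not counted, that of kn1 ranked 1 of 144 in ear (adjusted p = 0.012), 1 of 140 in SAM (adjusted p = 0.0022) and 2 of 143 in tassel (adjusted p = 7.1e-05). In leaf the window of kn1 ranked 1 of 148 in heterozygotes, with 2 genes called, and 2 of 148 in homozygotes. It passed in neither (adjusted p = 0.51 and 0.57). Genes within 100 of kn1 called in both tassel and ear moved the same way in 35 of 38 cases against 365 of 552 elsewhere (Fisher exact p = 0.00049). Sequence differences from the reference that lower read counts, altered transcription from the segment and effects of kn1 on its neighbours, among them adh1 and GIF1, all stay open, since none was tested here.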
